A study of Homo sapiens with 6 samples.

How the data were processed

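Poly(A) or ribosomal RNA selection is not stated in the labels; per the labels' protocols, total RNA of HaCaT cells was extracted with TRIzol and libraries were prepared with an Illumina TruSeq RNA kit. There were 6 libraries: 3 of the control group and 3 of the IQGAP2 knockdown group, which carried a short hairpin RNA. Groups were taken from the sample labels. The replicate numbers of the labels run from 1 to 3 in both groups, and nothing in the labels says that they pair libraries.

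The authors deposited a table of FPKM values (fragments per kilobase of gene, scaled by sequencing depth), with a row per gene and a column per library. Per the submitters' processing notes, HISAT2 2.2.1 and the GRCh38 build were used. The counting program, the annotation, the gene lengths and whether counting used strand are not given in the sources used here. The table held 12829 genes, and every gene had a mean over the 6 libraries of at least 0.1 FPKM, so that genes below this are not analysed here. Of these genes 12818 matched GENCODE v29 by identifier, and 12806 were protein coding there. FPKM divides by the library total, so a fall of abundant transcripts raises all others, and reads of near-identical copies and of overlapping genes may have been divided or dropped in a way that cannot be seen from the table.

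Within a gene, FPKM values were whole multiples of a common step once each library was scaled by its relative depth. Whole reads were recovered from this for all 12829 genes, within a tolerance of 0.004 reads, and summed to 15122470, 14018326 and 13957447 in control replicates 1, 2 and 3 and to 12901037, 15360759 and 13827320 in knockdown replicates 1, 2 and 3. A divisor common to all 6 counts of a gene cannot be seen. For 85.0% of genes the length in GENCODE v29 and the recovered reads implied a total for control replicate 1 within 10% of the median over genes. On 3000 simulated genes the exact reads were recovered for 98.3%. Recovered reads served for depth, for the agreement of libraries and for the interval of IQGAP2 (exact Clopper-Pearson, 95%), and were used in an alternative test; FPKM values were used in the main test. Intervals cover counting error only, since reads without molecular identifiers are not independent molecules.

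No library was a repeat of another: over 10718 genes with a mean of at least 50 reads, the chi-square of reads per degree of freedom was 2.10 or more within groups. Over 6075 genes with a mean of at least 500 reads, the variation beyond counting noise was 3.23% in control libraries, 7.23% in knockdown libraries and 3.27% in knockdown libraries without replicate 2. The correlation of log2 values across genes was 0.9970 to 0.9973 within control, 0.9931 to 0.9968 within knockdown and 0.9628 to 0.9748 between groups.

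The comparison of knockdown with control was made with limma 3.58.1 in R 4.3.3, on log2(FPKM + 1), for the 11214 genes with a mean of at least 0.5 FPKM over the 6 libraries, with group as the only factor. Moderated variances followed a mean-variance trend, tests were two-sided, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. IQGAP2 lay below this filter and was tested in the same model with IQGAP2 added, together with an exact two-sided permutation test. The other 1614 genes below the filter were tested only in the alternative without a filter. Gene lists were tested with camera of limma, with a preset correlation between genes of 0.01, for lists with at least 5 tested genes, and adjusted over the 31 lists that had them. The test was repeated with the correlation estimated from the data. Of 37 lists fixed, the IQGAP family and 5 lists of other cell types had fewer genes. Genes given in 2 lists counted in both.

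The groups, the tests, the gene lists, the rule for naming genes and most alternative settings were fixed before the data were examined. The rule named IQGAP1, IQGAP2 and IQGAP3; the 8 largest rises and 8 largest falls by log2 change among genes past the threshold whose groups did not overlap; for each list past the camera threshold its 3 members past the threshold with the largest change, and for each other list with at least 3 such members the largest 2; and, whatever their p, MTOR, KRT5, KRT14, KRT1, KRT10, MKI67 and the member with the highest mean of each list of another cell type. The results of 1 list that did not pass, with its named genes, and of 1 further named gene are not reported here.

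On reads simulated for the same comparison over 11177 genes, with a variation of 7.23% between replicates, limma recovered 98.5% of 67 genes changed by 1.5-fold, 100% of 67 changed by 2-fold and 97.0% of 66 changed by 4-fold, and called 18 of 10940 unchanged genes. A simulated list moved by 1.3-fold passed camera and 0 of 30 unmoved lists did; genes of the simulated lists varied independently, so this does not test correlated genes.

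The alternatives set beforehand were pseudocounts of 0.1 and 0.5; no filter on low values and a filter at a mean of 5 FPKM; rescaling of each library to a common sum, median-of-ratios scaling and quantile normalization; no variance trend, and a robust trend; array weights; the replicate number as a block; each library left out in turn; a test against a minimum fold of 1.5; and, for lists, the estimated correlation, fry and camera on ranks. After the data were seen, voom on the recovered reads, removal of each library's trend over transcript length (loess with a span of 0.3), removal of its trends over transcript length and GC content, and leaving mitochondrial reads out of the denominator were added. Transcript length was the union of a gene's exons and GC content that of its longest transcript, in GENCODE v29, known for 11209 of the tested genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.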

Results

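RNA-seq libraries from HaCaT cells, an immortalised and aneuploid human keratinocyte line that is widely used as a model of the epidermis, were compared between 3 control libraries, labelled as normal control, and 3 libraries of cells carrying a short hairpin RNA against IQGAP2. IQGAP2 is a scaffold protein of the IQGAP family, which binds calmodulin and actin. The series title names cell proliferation and the mTOR pathway as the matters of interest, so the comparison addresses which transcripts differ when IQGAP2 is knocked down, with those of the mTOR pathway and the cell cycle among them. Expression was given as FPKM for 12829 genes. The whole reads behind these values could be recovered, and amounted to between 13957447 and 15122470 per library in the control group and between 12901037 and 15360759 in the knockdown group. Values below are the mean FPKM ± SD over the 3 libraries of a group (n = 3) unless stated otherwise. Log2 changes are knockdown minus control on the log2(FPKM + 1) scale, which understates the change of low genes, and adjusted p-values are those of limma. The labels call the libraries biological replicates but do not say that they came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Whether the control cells carried a non-targeting hairpin, and how many hairpins were used, is not stated in the labels.

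IQGAP2 (ENSG00000145703, GRCh38 chromosome 5, 76403249 to 76708132, plus strand) was low in the control cells and lower in the knockdown cells. Its level was 0.196 ± 0.00547 FPKM in control and 0.0235 ± 0.00808 FPKM in knockdown libraries. The 3 control libraries held 24, 22 and 21 reads of IQGAP2 and the 3 knockdown libraries held 2, 4 and 2, in replicate order. Corrected for depth, 12.2% of the control level remained, with an exact 95% interval of 5.07% to 25.5% that covers counting error only. In limma the log2 change was -0.22 (SE 0.072, adjusted p = 0.0217), and the exact two-sided permutation test gave p = 0.1, the smallest p that 3 libraries against 3 allow. The limma call rests on few reads and was lost when any control library, or knockdown replicate 3, was left out (adjusted p 0.0519 to 0.0556, with a range over all alternatives of 4.70e-05 to 0.0556). The related gene IQGAP1 (ENSG00000140575) was higher in the knockdown, at 49.1 ± 3.38 FPKM against 31 ± 1.11 FPKM (log2 change 0.65, SE 0.056, adjusted p = 1.17e-05). IQGAP3 (ENSG00000183856) was at 14 ± 0.776 FPKM in knockdown and 14.8 ± 0.0691 FPKM in control libraries and did not pass the test (log2 change -0.07, SE 0.054, adjusted p = 0.256), with a change of 0.09 once values were rescaled to a common sum. The IQGAP3 difference passed without knockdown replicate 2 (log2 change -0.12, adjusted p = 0.0377) and with the trend over transcript length removed (-0.13, adjusted p = 0.0344), with a range over all alternatives of 0.0344 to 0.489.

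**Figure D1:**
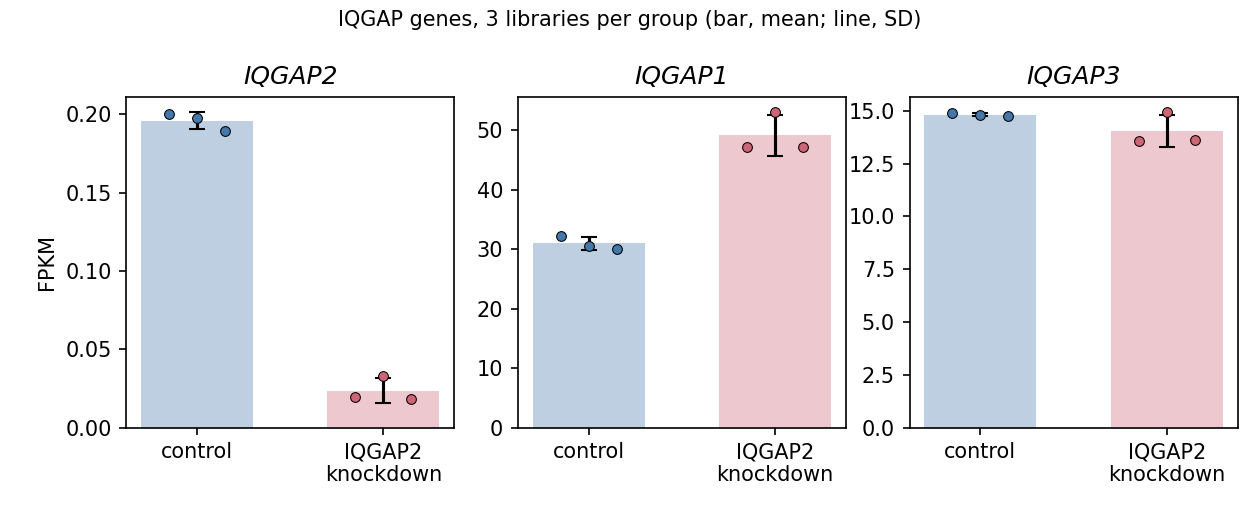
FPKM of the 3 IQGAP genes in each library (points), with the group mean (bar) and SD (line), in control and IQGAP2 knockdown cells; each panel has its own axis, starting at 0. The 3 knockdown libraries lie below the 3 control libraries for IQGAP2 and above them for IQGAP1.

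The knockdown libraries differed from the controls over much of the transcriptome. Of 11214 genes tested, 3313 were higher and 3121 lower in the knockdown, together 57.4%. Most changes were small: 93 genes were higher and 94 lower by over 2-fold on the log2(FPKM + 1) scale. The control and knockdown values did not overlap for 7303 genes (65.1%), against 10% by chance. FPKM summed to between 271372 and 274709 in control libraries and between 234624 and 248082 in knockdown libraries, so that rescaling each library to a common sum raised the median change of all genes from 0.01 to 0.17 and gave 4872 higher and 1845 lower genes (72.5% of the calls higher, against 51.5%). Changes below are for the values as deposited, and counts of higher and lower genes within a list shift with this scaling too. Knockdown replicate 2 stood apart from the other knockdown libraries, with a chi-square per degree of freedom of 11.3 and 10.5 against them, while knockdown replicates 1 and 3 and the control pairs gave 2.10 to 2.49. The median change of genes rose with transcript length, from -0.19 in the shortest decile of genes to 0.18 in the longest, and knockdown replicate 2 differed from replicates 1 and 3 by the same kind of trend, from -0.14 to 0.12.

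**Figure D2:**
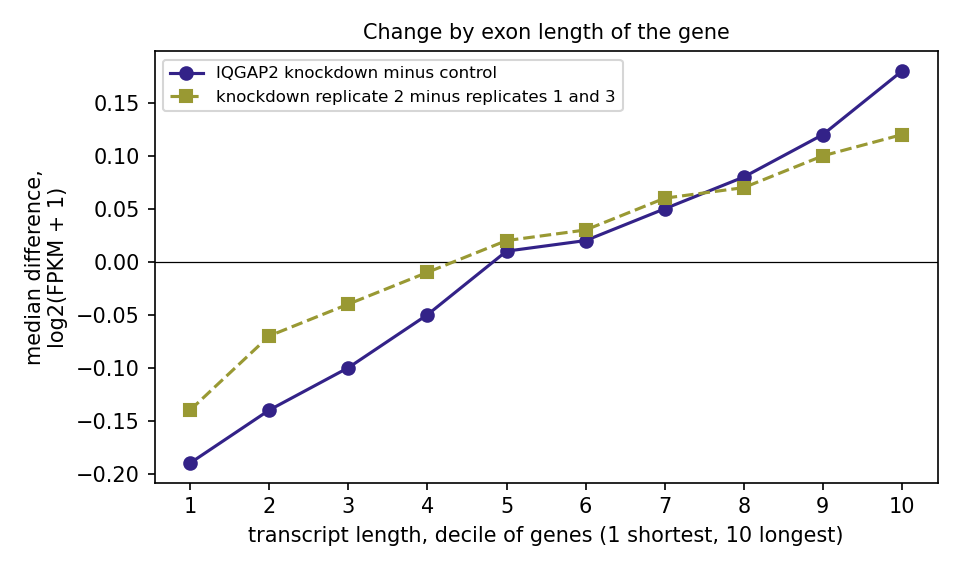
Median difference in log2(FPKM + 1) over genes grouped by transcript length, from the shortest decile (1) to the longest (10), for knockdown minus control (solid line) and for knockdown replicate 2 minus the mean of knockdown replicates 1 and 3 (dashed line). Both lines run upwards, from -0.19 to 0.18 and from -0.14 to 0.12.

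The largest rise was that of KRT1 (ENSG00000167768), the keratin of differentiating suprabasal keratinocytes, from 1.14 ± 0.274 to 34.4 ± 0.7 FPKM (log2 change 4.06, SE 0.088, adjusted p = 1.45e-09). DHRS2, a short-chain dehydrogenase, rose from 0.551 ± 0.207 to 9.69 ± 0.506 FPKM. The arrestin-domain genes TXNIP and ARRDC4, both known as genes induced by glucose through MondoA and ChREBP, rose from 55.8 ± 1.66 to 303 ± 13.8 FPKM and from 7.09 ± 1.01 to 30.6 ± 1.53 FPKM. The cornified envelope genes SPRR1A and SPRR2E reached 146 ± 23.5 FPKM from 29.7 ± 3.89 and 5.90 ± 0.409 FPKM from 0.822 ± 0.267. Histone genes H2AC6 and H2BC11 rose from 9.77 ± 0.574 to 46.9 ± 1.42 FPKM and from 2.21 ± 0.478 to 11.8 ± 1.70 FPKM. The largest fall was that of CCL2 (ENSG00000108691), a chemokine that attracts monocytes, from 40.7 ± 0.138 to 2.63 ± 0.144 FPKM (log2 change -3.52, SE 0.053, adjusted p = 1.69e-10). PLAT, the tissue plasminogen activator, fell from 34.4 ± 0.390 to 4.15 ± 0.173 FPKM. Among matrix metalloproteinases, MMP12 fell from 12.2 ± 0.139 to 1.05 ± 0.422 FPKM and MMP7 from 39.6 ± 0.675 to 8.47 ± 0.506 FPKM. The acute-phase gene SAA1 fell from 140 ± 5.90 to 25.3 ± 2.45 FPKM and the antimicrobial peptide gene DEFB1 from 6.74 ± 1.14 to 0.659 ± 0.534 FPKM. SOX2, a transcription factor of stem cells, fell from 14.3 ± 0.562 to 2.38 ± 0.488 FPKM, and TCIM, a regulator of WNT signalling, from 13.9 ± 0.966 to 2.55 ± 0.236 FPKM. These 16 genes were chosen among those past the threshold whose groups did not overlap, so a change larger than the spread between replicates follows from the choice. The highest adjusted p was 1.20e-05, for DEFB1. SPRR, histone and SAA genes have near-identical copies, so how reads were divided among them is uncertain.

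**Figure D3:**
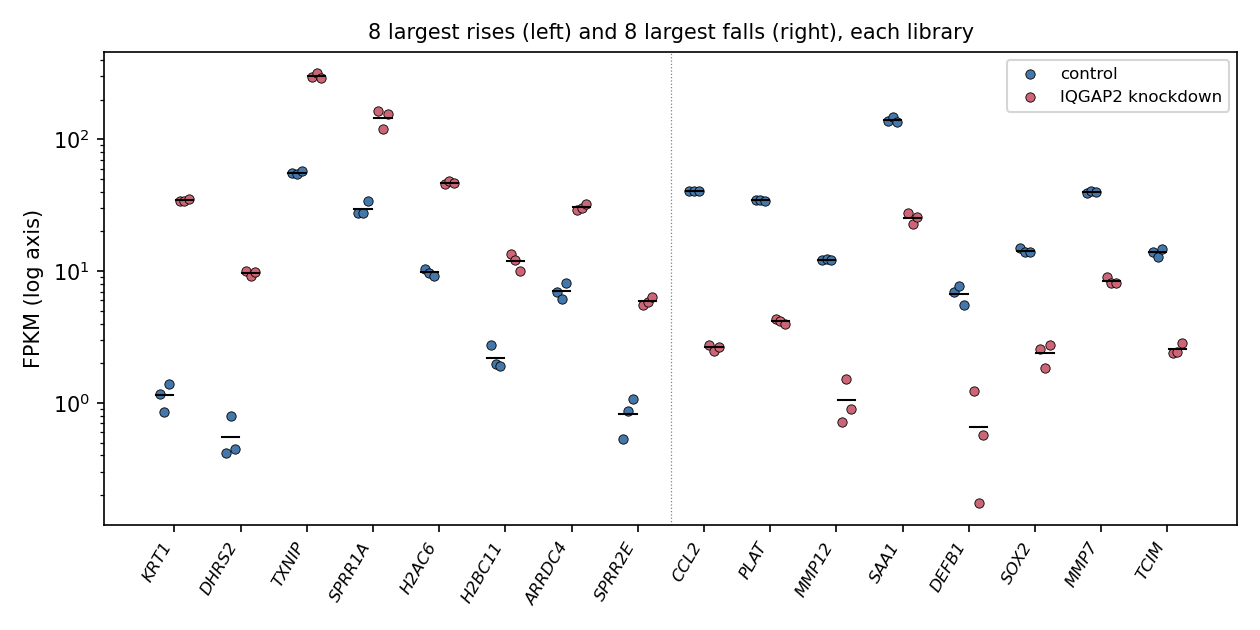
FPKM on a log axis of the 8 genes with the largest rise (left) and the 8 with the largest fall (right), each point a library and each short line a group mean over 3 libraries. Control and knockdown libraries do not overlap for any of the 16 genes, by the rule that chose them. KRT1 goes from a mean of 1.14 to 34.4 FPKM and CCL2 from 40.7 to 2.63 FPKM.

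In groups of genes fixed beforehand, 15 of 31 lists tested passed the camera test with a preset correlation between genes, 8 of them upwards and 7 downwards. In the other splits of the 6 libraries into 3 and 3, where no gene was called, 8 to 11 lists passed the same test. Those splits mix the groups unevenly, so part of the real difference remains in each. They cannot show how often a list passes without a difference, so passing carries an unknown weight for any single list. With an estimated correlation none of the 15 passed, the lowest adjusted p being 0.0578. The interferon, keratinocyte differentiation and ATF4 lists, at that p, had estimated correlations of 0.007, 0.004 and -0.003. These lie below the preset 0.01, so a higher correlation between genes is not why these lists lost the call. The same holds for the sterol synthesis and the G1/S and DNA replication lists, at -0.024 and -0.001. The other lists that passed had estimates of 0.03 to 0.638, so for them a higher correlation may be part of the reason. Counts of members below are over all genes tested, and those adjusted over the list alone follow where they differ. Each gene said to have risen or fallen passed the limma test over all genes.

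Genes of keratinocyte differentiation rose as a group: of 43 tested, 27 were higher and 5 lower, 28 and 6 adjusted over the list alone. The median change was 0.47 (camera adjusted p = 3.87e-06, and adjusted p = 0.0578 with an estimated correlation). Beside KRT1, SPRR1A and SPRR2E, its partner keratin KRT10 rose from 6.80 ± 0.326 to 14 ± 1.71 FPKM (adjusted p = 1.22e-05). In the list of stress keratins and alarmins, 11 of 16 members were higher and 3 lower (median 0.51, camera adjusted p = 0.00384, and adjusted p = 0.182 with an estimated correlation), and with only genes of at least 5 FPKM the list did not pass (adjusted p = 0.0816, with a range over all alternatives with camera of 8.69e-05 to 0.182). The calcium-binding alarmins S100A8 and S100A12 rose from 12.7 ± 1.36 to 45.5 ± 3.87 FPKM and from 0.338 ± 0.229 to 3.86 ± 0.726 FPKM, while the iron-binding lipocalin LCN2 fell from 431 ± 13.6 to 115 ± 16.7 FPKM. Basal keratinocyte genes did not pass as a list (10 of 19 higher, 2 lower, median 0.17, camera adjusted p = 0.0907), although they did once values were rescaled to a common sum (adjusted p = 0.0192) or quantile normalized (adjusted p = 0.0033, with a range over all alternatives with camera of 0.0033 to 0.408). With the length trend removed, 8 of these long genes were higher and 4 lower (median 0.03, camera adjusted p = 0.221). The hemidesmosome genes COL17A1 and ITGA6 rose from 125 ± 0.268 to 260 ± 18.5 FPKM and from 74.7 ± 1.51 to 139 ± 14.3 FPKM. KRT5 rose from 1150 ± 3.61 to 1480 ± 62.8 FPKM (log2 change 0.37, adjusted p = 6.16e-04). KRT14 was at 2570 ± 62.0 FPKM in control and 2310 ± 190 FPKM in knockdown libraries and did not pass (log2 change -0.16, adjusted p = 0.117). Its sign depended on the processing, with a change of 0.01 under a common sum. KRT14 passed as lower without knockdown replicate 2 (log2 change -0.09, adjusted p = 0.0157) and with voom (-0.16, adjusted p = 0.0166). It passed as higher with quantile normalization (0.63, adjusted p = 4.30e-07) and with the length and GC trends removed (0.12, adjusted p = 0.0405). The highest adjusted p over all alternatives was 0.91. No direction is given for KRT14. Of 6 simple epithelial keratins, 2 were higher and 4 lower (median -0.50, camera adjusted p = 0.211), with KRT4 rising from 27.3 ± 0.713 to 47.5 ± 1.62 FPKM and KRT13 falling from 125 ± 3.74 to 80.1 ± 1.23 FPKM.

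Targets of YAP and TEAD, the transcriptional effectors of the Hippo pathway, were higher: 18 of 23 tested rose and 1 fell, 19 and 1 adjusted over the list alone (median 0.55, camera adjusted p = 7.53e-06, and adjusted p = 0.183 with an estimated correlation). AJUBA rose from 30.8 ± 0.808 to 80.2 ± 10.9 FPKM, AMOTL2 from 16.2 ± 0.294 to 38.7 ± 1.86 FPKM and the tissue factor gene F3 from 328 ± 4.09 to 737 ± 37.2 FPKM. Of 10 EGF family ligands, receptors and regulators, 8 rose and none fell (median 0.58, camera adjusted p = 1.04e-04, and adjusted p = 0.189 with an estimated correlation). AREG rose from 19.5 ± 1.19 to 53.6 ± 4.05 FPKM, EREG from 2.78 ± 0.176 to 5.86 ± 0.842 FPKM and the receptor EGFR from 29.6 ± 0.842 to 49.4 ± 4.90 FPKM. AP-1 and immediate early genes went both ways, 16 of 28 higher and 9 lower (median 0.24, camera adjusted p = 0.155). DUSP4 and PHLDA1 in this list rose from 3.37 ± 0.208 to 8.55 ± 0.448 FPKM and from 44.9 ± 0.608 to 96.3 ± 2.43 FPKM.

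Interferon-stimulated genes rose, with 32 of 45 higher and 5 lower, 33 and 5 adjusted over the list alone (median 0.53, camera adjusted p = 4.31e-09, and adjusted p = 0.0578 with an estimated correlation). RSAD2 went from 45.8 ± 1.82 to 132 ± 5.54 FPKM, ISG15 from 703 ± 32.2 to 1750 ± 175 FPKM and XAF1 from 4.89 ± 0.360 to 12.8 ± 2.10 FPKM. In the list of NF-kB and inflammatory cytokine genes 12 of 30 were higher and 11 lower (median -0.02, mean 0.01, camera adjusted p = 0.882), and 15 higher and 6 lower with values rescaled to a common sum (median 0.14). CCL2 fell, as given above, and the neutrophil chemokine gene CXCL2 rose from 4.35 ± 0.803 to 13.4 ± 2.50 FPKM.

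Lists of stress responses went in both directions. Genes of the ATF4 and amino acid response rose, 18 of 27 higher and none lower (median 0.31, camera adjusted p = 4.85e-06, and adjusted p = 0.0578 with an estimated correlation). With values rescaled to a common sum the median was 0.50. TRIB3 rose from 53.4 ± 1.4 to 139 ± 4.98 FPKM, the cystine transporter SLC7A11 from 7.80 ± 0.426 to 16.3 ± 2.25 FPKM and STC2 from 38.9 ± 0.238 to 73.9 ± 0.381 FPKM. Genes of the hypoxia response rose, 16 of 21 higher and 3 lower (median 0.42, camera adjusted p = 0.00112, and adjusted p = 0.182 with an estimated correlation), among them VEGFA from 25.7 ± 0.441 to 43.8 ± 3.76 FPKM, CA12 from 0.549 ± 0.0183 to 1.45 ± 0.0783 FPKM and BNIP3 from 44.1 ± 0.933 to 66.4 ± 2.59 FPKM. These genes are long, and the median was 0.24 with the length trend removed and 0.28 with the length and GC trends removed (camera adjusted p = 0.00124 and 0.00123). Heat shock genes fell, 13 of 15 lower and 1 higher (median -0.48, camera adjusted p = 1.66e-06, and adjusted p = 0.108 with an estimated correlation). The chaperone genes HSPA8, HSPA1A and HSPB1 fell from 297 ± 0.715 to 116 ± 0.146 FPKM, from 39.9 ± 0.345 to 16.3 ± 1.44 FPKM and from 905 ± 3.86 to 426 ± 75.5 FPKM. NRF2 targets, genes of the antioxidant response, were lower, 14 of 24 lower and 4 higher, 14 and 5 adjusted over the list alone (median -0.34, camera adjusted p = 0.00722, and adjusted p = 0.183 with an estimated correlation). The median was -0.18 with the length trend removed, -0.15 with the length and GC trends removed and -0.19 with values rescaled to a common sum (camera adjusted p = 0.0225, 0.0203 and 0.00153). The aldo-keto reductases AKR1B10 and AKR1C2, members of a family of similar sequences, fell from 3.31 ± 0.646 to 0.552 ± 0.182 FPKM and from 24.5 ± 0.588 to 9.65 ± 0.505 FPKM. SLC7A11, given above, is also in this list and rose. In the unfolded protein response 11 of 21 were higher and 6 lower, 13 and 6 adjusted over the list alone (median 0.21, camera adjusted p = 0.104), with CANX rising from 48.3 ± 0.791 to 95.9 ± 5.05 FPKM and SEL1L from 7.58 ± 0.181 to 15.2 ± 1.95 FPKM. Of 22 p53 targets, 10 were higher and 4 lower (median 0.12, camera adjusted p = 0.105), GADD45A rising from 59.5 ± 0.776 to 186 ± 6.17 FPKM and TP53I3 from 1.56 ± 0.0333 to 3.25 ± 0.274 FPKM.

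Transcripts of the respiratory chain and the ribosome were lower. Of 42 nuclear genes of oxidative phosphorylation tested, 35 fell and 1 rose, 36 and 1 adjusted over the list alone (median -0.50, camera adjusted p = 4.94e-11, and adjusted p = 0.183 with an estimated correlation). The cytochrome c oxidase subunits COX7B, COX6B1 and COX8A fell from 47.4 ± 2.45 to 18.8 ± 2.19 FPKM, from 58.3 ± 1.43 to 24.3 ± 3.26 FPKM and from 16.3 ± 3.18 to 7.46 ± 0.842 FPKM. All 13 mitochondrially encoded genes fell (median -0.97, camera adjusted p = 2.72e-07, and adjusted p = 0.189 with an estimated correlation). With quantile normalization 10 were lower (median -0.60, camera adjusted p = 1.96e-05). MT-ND4 fell from 4830 ± 153 to 1900 ± 305 FPKM, MT-ATP6 from 2680 ± 102 to 983 ± 152 FPKM and MT-ND6 from 1390 ± 76.5 to 409 ± 60.7 FPKM, the latter being encoded on the opposite strand to its neighbours, so that its reads cannot be separated from theirs where counting ignores strand. Together these 13 genes took 4.34% to 4.64% of the recovered reads in control libraries and 2.05% to 2.44% in knockdown libraries. Of 78 ribosomal protein genes, 49 fell and 4 rose, 50 and 5 adjusted over the list alone (median -0.25, camera adjusted p = 2.37e-07, and adjusted p = 0.489 with an estimated correlation); with values rescaled to a common sum 34 fell and 12 rose (median -0.10). RPS15, RPS25 and RPL38 fell from 376 ± 2.13 to 196 ± 32.5 FPKM, from 457 ± 16.4 to 254 ± 19.0 FPKM and from 51.3 ± 3.68 to 28.0 ± 2.50 FPKM. Genes of these lists were short, with a median exon length of 784 bases for the mitochondrially encoded, 3055.5 for the ribosomal protein and 3148.5 for the nuclear oxidative phosphorylation genes, and all tested genes of 2913 to 3606 bases had a median change of -0.10. Knockdown replicate 2 lay farthest from the controls: its median over the ribosomal protein genes was -0.44, against -0.21 in both other knockdown libraries. Without it the medians were -0.44 for nuclear oxidative phosphorylation, -0.93 for the mitochondrially encoded genes and -0.20 for the ribosomal protein genes.

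Components of the mTOR pathway did not pass as a list. Of 54 tested, 14 were higher, 13 lower and 27 did not pass (median -0.07, camera adjusted p = 0.651). The balance depended on the processing: 18 were higher and 7 lower with values rescaled to a common sum (median 0.08), and 8 higher and 19 lower with the length trend removed (median -0.09). The list passed camera in neither (adjusted p = 0.922 and 0.274). MTOR itself (ENSG00000198793) was at 5.50 ± 0.202 FPKM in control and 7.02 ± 0.546 FPKM in knockdown libraries (log2 change 0.30, SE 0.068, adjusted p = 0.00379). MTOR is a long transcript, and once the trend over transcript length was removed its difference did not pass (log2 change 0.14, adjusted p = 0.0644, with a range over all alternatives of 5.68e-04 to 0.0644). With the trends over length and GC content both removed it passed (log2 change 0.19, adjusted p = 0.0174). On the log2(FPKM + 1) scale the largest changes within the list were rises of SESN2, a stress-induced inhibitor of mTOR complex 1, from 15.2 ± 0.409 to 29 ± 0.684 FPKM (adjusted p = 4.80e-07), and of IRS1, an adaptor of the insulin receptor, from 4.09 ± 0.109 to 6.78 ± 0.340 FPKM (adjusted p = 3.48e-05). By the ratio of FPKM the largest was the fall of DEPTOR, an inhibitor of mTOR named after its values were seen, from 0.754 ± 0.0302 to 0.317 ± 0.0416 FPKM (2.38-fold, adjusted p = 9.07e-04). RNA levels do not measure the pathway's activity, which acts through phosphorylation.

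Of the cell cycle lists, that of G1/S and DNA replication passed as lower and that of G2/M and mitosis did not pass. In the list of G1/S and DNA replication 21 of 45 were lower and 4 higher (median -0.16, camera adjusted p = 0.00237, and adjusted p = 0.108 with an estimated correlation), and 14 lower and 9 higher with values rescaled to a common sum (median -0.01). The replication licensing factor CDT1 fell from 44.2 ± 1.69 to 22.4 ± 1.60 FPKM, and the polymerase subunits POLD1 and POLE2 from 17.2 ± 0.820 to 11 ± 0.978 FPKM and from 9.19 ± 0.316 to 5.99 ± 0.881 FPKM. In the list of G2/M and mitosis 16 of 38 were higher and 6 lower (median 0.05, camera adjusted p = 0.349), and 22 higher and 4 lower with values rescaled to a common sum (median 0.22). AURKB, the kinase of the chromosomal passenger complex, fell from 68.4 ± 1.25 to 37.3 ± 3.99 FPKM and HMMR rose from 20.7 ± 0.429 to 34.5 ± 1.07 FPKM. MKI67, the proliferation marker Ki-67, was at 33.0 ± 0.288 FPKM in control and 30.7 ± 1.22 FPKM in knockdown libraries and did not pass (log2 change -0.10, SE 0.046, adjusted p = 0.0927), with a change of 0.07 once values were rescaled to a common sum. MKI67 passed as lower without knockdown replicate 2 (log2 change -0.13, adjusted p = 0.0105), with array weights (-0.12, adjusted p = 0.0156) and with mitochondrial reads left out of the denominator (-0.13, adjusted p = 0.0329). It also passed with the length trend removed (-0.27, adjusted p = 2.56e-04) and with the length and GC trends removed (-0.26, adjusted p = 2.10e-04). The highest adjusted p over all alternatives was 0.481. Replication-dependent histone genes rose, 20 of 27 higher and none lower (median 0.72, camera adjusted p = 6.13e-06, and adjusted p = 0.108 with an estimated correlation). Beside H2AC6 and H2BC11, H2BC12 rose from 30.8 ± 2.38 to 66.9 ± 1.48 FPKM. Most messages of these genes lack a poly(A) tail, so their level depends on how RNA was selected.

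Of the metabolic lists, that of sterol synthesis passed. Its genes fell, 14 of 24 lower and 3 higher, 15 and 3 adjusted over the list alone (median -0.26, camera adjusted p = 0.00432, and adjusted p = 0.117 with an estimated correlation). With values rescaled to a common sum 9 were lower and 6 higher (median -0.14, camera adjusted p = 0.00567). DHCR7 and EBP, enzymes of late cholesterol synthesis, fell from 12.7 ± 0.880 to 6.70 ± 0.380 FPKM and from 14.2 ± 0.881 to 7.93 ± 0.710 FPKM. Of 13 genes of fatty acid synthesis 6 were higher and 1 lower (median 0.17, camera adjusted p = 0.147): SCD rose from 59.0 ± 0.313 to 104 ± 8.90 FPKM and FASN fell from 23.9 ± 0.413 to 17.6 ± 1.52 FPKM. Among 19 glycolysis genes 8 were higher and 5 lower (median 0.07, camera adjusted p = 0.396), with HK2 rising from 12.5 ± 0.228 to 23.3 ± 1.33 FPKM and PFKM falling from 14.6 ± 0.196 to 8.30 ± 0.380 FPKM. Of 29 autophagy and lysosome genes 10 were higher and 11 lower, 10 and 12 adjusted over the list alone (median 0.05, mean -0.02, camera adjusted p = 0.882), and 15 higher and 4 lower with values rescaled to a common sum (median 0.22). The lysosomal proteases CTSB and CTSD fell from 106 ± 1.06 to 52.5 ± 0.570 FPKM and from 58.9 ± 0.761 to 41.1 ± 5.54 FPKM.

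Lists of adhesion, matrix, WNT signalling and mesenchymal transition did not pass. Among 31 cell adhesion and junction genes 14 were higher and 8 lower, 14 and 10 adjusted over the list alone (median 0.07, camera adjusted p = 0.147), the desmosomal cadherins DSC2 and DSG3 rising from 6.07 ± 0.178 to 14.1 ± 1.52 FPKM and from 50.3 ± 1.08 to 106 ± 8.11 FPKM. The list of TGF-beta response and extracellular matrix had 15 of 32 lower and 8 higher, 15 and 9 adjusted over the list alone (median -0.12, camera adjusted p = 0.139), with THBS1 rising from 22.6 ± 0.370 to 79.5 ± 8.45 FPKM and MMP13 falling from 35.9 ± 0.864 to 7.94 ± 1.36 FPKM. Of 30 WNT pathway genes 12 were higher and 5 lower (median 0.03, camera adjusted p = 0.211); the inhibitor DKK1 rose from 31 ± 1.13 to 63.9 ± 3.10 FPKM and WNT4 fell from 12.4 ± 0.317 to 6.74 ± 0.967 FPKM. In the list of mesenchymal transition 3 of 9 were higher and 4 lower (median -0.13, mean 0.06, camera adjusted p = 0.897). SNAI2 rose from 27.2 ± 1.86 to 70.2 ± 7.93 FPKM and TWIST2 fell from 6.18 ± 0.649 to 3.56 ± 0.698 FPKM.

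**Figure D4:**
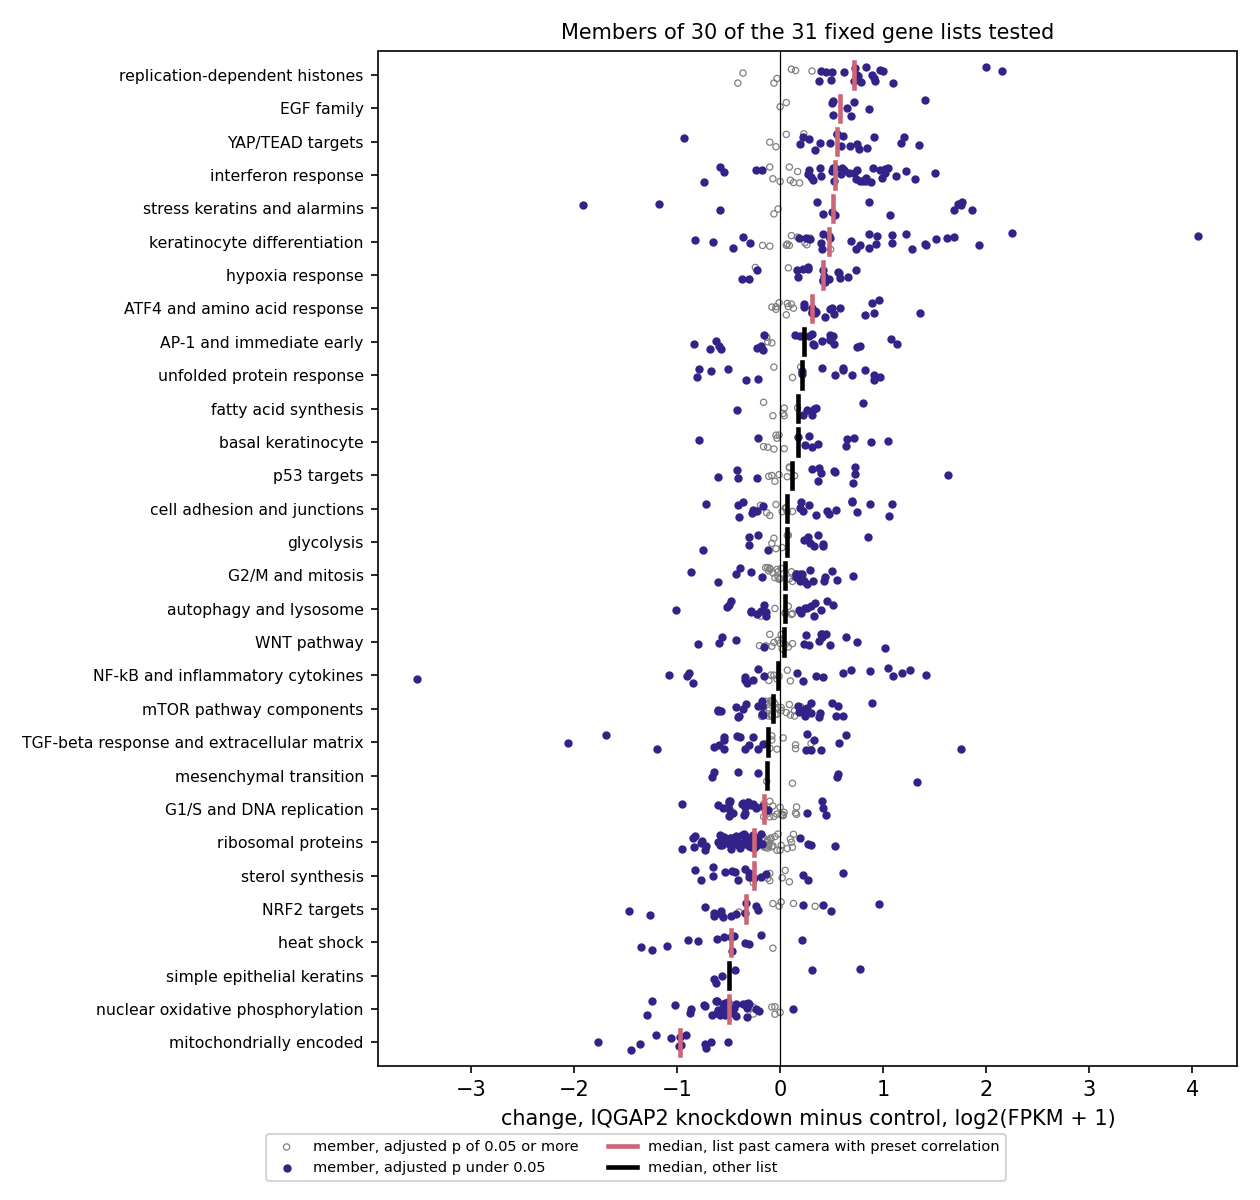
Log2 change (knockdown minus control, on the log2(FPKM + 1) scale) of every tested member of 30 of the 31 fixed lists tested, filled points having an adjusted p under 0.05; thick lines mark list medians, red for the 15 lists past camera with the preset correlation. Medians run from -0.97 for the mitochondrially encoded genes to 0.72 for replication-dependent histones.

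Few markers of other cell types that could be present in a culture reached the level tested. Of 12 fibroblast markers 4 were in the table and 3 tested; MFAP5 rose from 1.08 ± 0.125 to 3.42 ± 0.241 FPKM and LUM, named after its values were seen, fell from 2.21 ± 0.346 to 0.268 ± 0.134 FPKM. The melanocyte marker PMEL was at 0.886 ± 0.0747 FPKM in control and 0.725 ± 0.0998 FPKM in knockdown libraries (adjusted p = 0.184), and was the 1 tested of 8 melanocyte genes. Of 10 leukocyte genes 2 were tested, and both fell: CD74, the invariant chain of MHC class II, from 5.95 ± 0.451 to 1.38 ± 0.182 FPKM, and HLA-DRA, named after its values were seen, from 3.22 ± 0.0978 to 0.998 ± 0.118 FPKM. None of the 7 endothelial genes reached the level tested; VWF was at 0.142 ± 0.0311 FPKM in control and 0.423 ± 0.0528 FPKM in knockdown libraries. Of 8 genes of an embryonic kidney line 2 were tested. CKB was at 87.0 ± 1.74 FPKM in control and 90.7 ± 7.63 FPKM in knockdown libraries (adjusted p = 0.459), a difference that passed without knockdown replicate 2 (log2 change 0.13, adjusted p = 0.00567) and in 4 other alternatives (0.11 to 0.31), with a range of adjusted p over all alternatives of 3.86e-05 to 0.82. The other, NEFL, named after its values were seen, rose from 4.98 ± 0.399 to 7.75 ± 0.491 FPKM.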

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

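Of 97 named genes tested, 92 kept their direction and side of the threshold under each of the 20 or 21 alternatives run for them, which do not include the minimum fold; voom, the removal of trends and the mitochondrial denominator were chosen after the data were seen. With values rescaled to a common sum, 1845 genes were lower (3121 as deposited) and the median change of all genes moved from 0.01 to 0.17, because the sum of FPKM was lower in the knockdown libraries. Against a minimum fold of 1.5, 142 genes were higher and 135 lower, by the construction of that test, and 66 of the 92 named genes that differed in the first test (a different set of 92) still passed. Removal of the length and GC trends gave 3164 higher and 3073 lower genes, of which 4837 were among the 6434 first called and 4826 had the same direction. For IQGAP2 the change ranged from -2.86 (voom) to -0.21; leaving out 1 library gave -0.23 to -0.22, and the call was lost without any of the 3 control libraries or knockdown replicate 3, with fewer samples. No other named gene and no list lost its call when a library was left out. Of the 31 lists, 0 passed camera with an estimated correlation and 30 passed fry, which does not compare a list with other genes. Single genes that turned were IQGAP3 (0.09), KRT14 (0.01) and MKI67 (0.07) under the common sum, and KRT14 with quantile normalization (0.63) and with the length and GC trends removed (0.12); apart from the common sum, which shifts all genes, the cause was not tested. By the direction of camera, which need not be the sign of the median, lists that turned were autophagy and lysosome (median 0.22 with the common sum, -0.01 without both trends) and mesenchymal transition (0.12 without the length trend, 0.11 without both). By the direction of fry, NF-kB (-0.02) and mesenchymal transition (-0.13) turned. The cause was not tested. By the sign of the median alone, the common sum, which shifts all genes, also turned mTOR components (to 0.08), TGF-beta (0.02), mesenchymal transition (0.03) and NF-kB (0.14). The median of NF-kB, near 0, turned in 8 further settings, and that of autophagy also without knockdown replicate 1 (-0.04). AP-1 genes passed camera without both trends (adjusted p = 0.00905) and with quantile normalization (adjusted p = 0.049), over a range for camera of 0.00905 to 0.275. Glycolysis genes passed camera with quantile normalization (median 0.23, adjusted p = 0.0409), over a range for camera of 0.0409 to 0.489.

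With the replicate number as a block, 3167 genes were higher and 3024 lower, with 6079 of the 6434 genes first called among them. The IQGAP2 change was -0.22 (adjusted p = 0.0486), the same 15 lists passed, and no named gene changed its call. Same-numbered libraries did not deviate together: the correlations of their deviations from the group means were -0.07, -0.04 and 0.02. Depth limits the test of IQGAP2, with 2 to 24 reads per library.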

Other observations

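Groups of genes other than the fixed lists were formed from shared symbol stems, whether or not their genes were in those lists. These groups and their tests, as well as those on repeated libraries and chromosome segments, were chosen only after the result was seen. Of 131 stems with at least 10 tested genes, 13 passed camera with the preset correlation, and 5 of these also passed with the length and GC trends removed. With an estimated correlation the adjusted p was 0.835 for each of those 5. The passing stems RPL, RPS, COX, NDUFA and NDUFB largely repeat the ribosomal protein and oxidative phosphorylation lists, NDUFA and NDUFB being among the 5. MRPS, a stem of mitochondrial ribosomal proteins, is also among the 5. Of its 27 genes 20 fell and 1 rose (median -0.22, camera adjusted p = 8.17e-04, and 0.0154 with the trends removed). For MRPL 29 of 45 fell and 2 rose (median -0.24, camera adjusted p = 5.34e-04, and 0.18 with the trends removed). PSMB, USP, KDM and GOLGA also passed, but not with the trends removed. KLF and MMP hold some members of the AP-1 and TGF-beta lists. Kruppel-like transcription factors were higher: 11 of 13 KLF genes rose and 1 fell (median 0.49, camera adjusted p = 0.00208, and 0.00372 with the trends removed). KLF4, a regulator of epidermal barrier formation, rose from 27.2 ± 0.721 to 47.3 ± 2.63 FPKM and KLF11 from 1.82 ± 0.326 to 4.80 ± 0.546 FPKM, while KLF9 fell from 2.04 ± 0.176 to 1.19 ± 0.157 FPKM (n = 3 per group). Genes with the MMP stem were lower, 8 of 12 falling and 1 rising (median -0.59, camera adjusted p = 0.00208, and 0.0154 with the trends removed). The stem takes in MMP24OS, which is not itself a metalloproteinase. The falling MMP12, MMP7, MMP13, MMP1 and MMP10 all lie on chromosome 11 and may not change independently. MMP15 and MMP2 on chromosome 16 and MMP28 on chromosome 17 also fell. Beside MMP7, MMP12 and MMP13, MMP1 fell from 48.2 ± 0.560 to 14.3 ± 1.09 FPKM, and MMP14, which is bound to the membrane, rose from 110 ± 1.00 to 138 ± 4.42 FPKM.

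Genes of MHC class II antigen presentation were picked out by eye after their values were seen, and no test of them as a group was made. Of 7 with values in limma, 6 were lower and none higher, against 3121 lower of all 11214 genes. HLA-DRB1 fell from 7.04 ± 0.748 to 0.977 ± 0.349 FPKM, HLA-DQB1 from 10.5 ± 0.432 to 5.26 ± 0.687 FPKM and HLA-DMA from 1.62 ± 0.282 to 0.766 ± 0.252 FPKM, whereas HLA-DOB was at 1.03 ± 0.0593 FPKM in control and 0.978 ± 0.136 FPKM in knockdown libraries (adjusted p = 0.69). HLA-DRB1 and HLA-DRB5 share sequence and vary between people, so their levels are uncertain.

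The breadth of the change, 6434 of 11214 genes, was weighed against the trends between libraries, a repeated library and a chromosome change in HaCaT cells, which are aneuploid. With each library's trends over transcript length and GC content removed, 6237 genes were called. Of these, 4837 were among the 6434 first called, 4826 of them in the same direction, and the others were new calls. The 4826 argue against these trends, with length taken as the union of a gene's exons, as the whole source. The closest replicates of a group differed by a chi-square of 2.1 per degree of freedom, more than counting noise alone would give, which argues against copies of a single library. Over windows of 10 Mb of nuclear chromosomes with at least 12 genes of 5 FPKM or more, the largest median change was -0.26 on chromosome 22 from 10 to 20 Mb. The next were 0.25 on chromosome 7 and -0.25 on chromosome 8. None reached the 0.4 looked for. Smaller segments were not covered, and a change in copy number that moves expression by less than 0.4 could not be seen. A chromosome change is therefore not excluded. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05 (1 of 10 gave as many genes, the real one). The real split gave 6434 genes and the highest other 0, and for lists the real split gave 15 and the highest other 11. The other splits mix the groups unevenly and keep part of the real difference, so their counts are not those expected without one. Across genes the change went with transcript length (rho 0.3) and with GC content (rho -0.35). Differences between the groups in RNA quality or library preparation beyond such trends were not tested. Such differences, the hairpin's own effects, the handling of each cell line and loss of IQGAP2 may each be the source. With no further hairpin or rescue among the libraries they cannot be separated.

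The fall of genes of oxidative phosphorylation and the ribosome was weighed against the length and GC trends and against knockdown replicate 2. Once both trends were removed, the median of nuclear oxidative phosphorylation genes was -0.36 (SE between libraries 0.035) and that of mitochondrially encoded genes -0.74 (SE 0.077). Without knockdown replicate 2 they were -0.44 and -0.93. These values argue against that library, and against trends over length and GC content as measured here, as the whole source. Length was the union of a gene's exons, which can exceed the length of the expressed transcript. A trend over the expressed length was not tested, so for the nuclear genes it is not excluded. For ribosomal proteins the median was -0.20 (SE 0.024) without replicate 2, which argues against that library alone. With the trends removed it was -0.21 (SE 0.074) and the list still passed camera (adjusted p = 2.12e-04). This median lay over 2 SE from 0, a criterion chosen after the result was seen. The stricter bound written beforehand, beyond -0.1 by 2 SE, was not met for this list. The stems RPL and RPS, which largely repeat the list, had medians of -0.22 and -0.13 with the trends removed. Neither then passed camera adjusted over all stems tested (adjusted p = 0.0579 and 0.224). These results differ, so whether the trends are the whole source for ribosomal proteins cannot be told. For nuclear oxidative phosphorylation and mitochondrially encoded genes the trends may still account for part of the fall. A biological hypothesis, that knockdown of IQGAP2 lowers respiratory chain transcripts, stays open beside the hairpin and line effects above.

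The rise of keratinocyte differentiation genes and of stress keratins and alarmins ran against the length trend, since these genes are short. With both trends removed the medians were 0.65 (SE 0.083) and 0.71 (SE 0.027), and the members of the differentiation list outside the SPRR, LCE and S100 families, 33 genes, had a median of 0.29 (SE 0.076). These values argue against the trends as the whole source for both lists. For the differentiation list alone they also argue against reads shared between near-identical copies as the whole source. Shared reads were not tested for the stress keratins and alarmins. Confluence and calcium, which induce such genes in keratinocytes, are not given per library in the labels, so a difference in culture between the groups stays open. That knockdown of IQGAP2 raises differentiation genes is a hypothesis that these values leave open, found and tested on the same data.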
